A study of Mus musculus with 11 samples.

How the data were processed

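Polyadenylated RNA was sequenced from CD8 T cells and tumour-associated macrophages sorted from PyMT mouse breast tumours of the FVB/NJ strain that had received 5 ng of GM-CSF or saline into the tumour. The 11 libraries form 4 groups: CD8 T cells with saline (n = 2), CD8 T cells with GM-CSF (n = 3), macrophages with saline (n = 3) and macrophages with GM-CSF (n = 3). Per the labels' protocols, the starting RNA was below the range that could be quantified, and a low-input mRNA kit amplified the cDNA over 21 cycles, took 10 ng of it into fragmentation and added 8 cycles of PCR. The labels name no molecular identifiers, so copies made by amplification count as separate reads, which widens the spread of genes with few transcripts. Per the series' design note, macrophage saline replicate 1 is a pool of cells from 2 tumours. Apart from that note, the labels do not say that the replicates are separate animals, so the p-values measure the spread between these samples.

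The deposited table holds log2(RPKM + 1) for 21073 genes listed by Entrez ID and symbol, with 0.0001 written where a gene has no reads. RPKM is the number of reads per kilobase of gene per 1e+06 reads, so the authors' values are already corrected for gene length and sequencing depth, and no further scaling between libraries was seen. The log2 unit was read from the values: after taking 2 to the power of the deposited value and subtracting 1, 40.5 to 56.1% of the ratios of low values of a gene, each library against CD8 saline replicate 1, were close to ratios of small whole numbers at the estimated depths. With the depths shifted, as a control for matches by chance, the share was 0.282 to 1.78%. Without the subtraction it was 0.929 to 6.52%. That last comparison adds little, since it reuses depths estimated with the subtraction and ratios of such low values then lie near 1. The mouse build mm10 and the programs Subread and featureCounts are named in the submitters' processing notes. Versions, parameters, strand setting and annotation are not given in the sources used here. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart. Genes with near-identical copies or pseudogenes, such as those for ribosomal proteins, mitochondrially encoded transcripts, Gapdh and the Ly6, H2-Q and immune receptor families, can lose or share reads and their levels are uncertain. Entrez IDs were matched to a RefSeq gene table of GRCm38.p6, the same assembly as mm10. Of these, 20857 matched and 216 did not, and coordinates come from that table. The table holds 2 symbols that occur more than once.

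Read depth was estimated from the smallest steps in the values, since a gene with 1 read has an RPKM set by the gene's length and the library's number of reads. Lengths were the summed exons of the GENCODE M21 annotation of GRCm38, which may differ from the lengths the authors used. In units of 1e+06 reads, the depth came to 11.8 and 20.6 for CD8 T cells with saline, 7.41, 10.2 and 8.86 for CD8 T cells with GM-CSF, 17.1, 15.5 and 22.3 for macrophages with saline, and 17.1, 19.8 and 15.3 for macrophages with GM-CSF. A read on a gene of 2 kb is then worth 0.0225 to 0.0675 RPKM. These depths are estimates, and counting error is the only error they describe. Beyond precision they were used to read the log2 unit from ratios of low values and to test the estimated reads of Ighd4-1.

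Tests used log2(RPKM + 1), computed from the back-transformed values, so fold changes are on the log2(RPKM + 1) scale and understate the change of genes near 1 RPKM. Before the data were examined, the tests, the gene lists, the rule for named genes and the alternatives were fixed on the assumption that the file held plain RPKM. The file holds the logarithm of that value, and the planned test was kept on the same scale. GM-CSF was compared with saline separately in each cell type with limma-trend (limma 3.58.1 in R 4.3.3), with empirical Bayes moderation and an intensity trend, over genes with a mean of at least 1 RPKM in the libraries of the fit. The difference of the GM-CSF effect between cell types was tested as an interaction contrast over all 11 libraries. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Lists were tested with limma's camera at a preset correlation between genes of 0.01, with the adjustment over the lists tested in that cell type, and lists with fewer than 5 measured members were left out. Camera asks whether the genes of a list moved further than the other genes. Camera with a correlation estimated for each list, and fry, which asks whether the genes of a list moved 1 way on balance, were the alternatives. With an estimated correlation camera takes its degrees of freedom from the few libraries, and with a preset one from the many genes. It therefore has little power here, and a call lost with it does not by itself show that genes of a list varied together.

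The 36 gene lists cover pathways, markers of cell types that a sort may carry over, and signs of RNA quality. Of these, 8 were offered to macrophages alone (pro-inflammatory activation, alternative activation, MHC class II presentation, angiogenic factors and inhibitors, chemokines, complement and phagocytosis, lysosome and lipid handling, monocyte genes), 5 to CD8 T cells alone (cytotoxic effector, exhaustion and checkpoint, naive and memory, activation and T cell receptor signalling, tissue residence and homing) and 23 to both. Macrophages had 31 lists and 26 were tested. CD8 T cells had 28 lists and 23 were tested. In both cell types the lists of CD8, endothelial, erythroid and fibroblast markers were too short after the filter on low values, as were NK cell markers in macrophages and neutrophil markers in CD8 T cells. Some genes stand in more than 1 list, such as Ccl5, Tnfrsf4 and Cxcl9, so the lists are not independent. To check the sort, the mean log2(RPKM + 1) over each of 12 marker lists was compared between the 6 macrophage and the 5 CD8 T cell libraries with an exact two-sided permutation test over all 462 splits, whose smallest possible p is 0.00433, with adjustment over the 12 lists (SciPy 1.17.1).

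Genes were named by a rule. Among genes past the threshold, the 10 with the largest positive and the 10 with the largest negative log2 change were named. Where these were fewer than 20, genes with the smallest unadjusted p were added until 20 were named, with as many higher as lower, provided that the libraries of the groups did not overlap, the mean reached 5 RPKM and the symbol was not that of a predicted or small RNA gene. These are given as values and not as changes. Each list past its threshold gave its 3 members with the smallest p, and each pathway list not past it gave 1 member. Csf2ra, Csf2rb, Flt1, Vegfa and Csf2 were always named in macrophages, and Gzmb, Prf1, Ifng, Pdcd1 and Csf2 in CD8 T cells. The interaction gave the 5 genes with the smallest p in each direction among those with a mean of at least 5 RPKM.

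Alternatives were a pseudocount of 0.1 or 5, no filter on low values, a mean of at least 5 RPKM, median-of-ratios scaling, quantile normalization, limma's arrayWeights, the replicate number as a block, all 11 libraries in 1 fit, and leaving out each library in turn. Leaving out V, D and J segments of immune receptors and the list tests on the interaction were chosen after the data had been seen. With CD8 saline replicates left out in turn, 1 saline library remains, and it is assumed to vary like the other group.

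The scripts were tested on simulated data with the real genes' means and fitted spreads. Over the 9172 genes of the macrophage comparison, 38.6% of genes changed 2-fold and 97.7% of genes changed 4-fold were found, and 7.21% of the calls were false. Over the 9468 genes of the CD8 T cell comparison, 30.2% and 95.4% were found, and 7.17% of the calls were false. A list moved by simulation was found in 10 of 10 simulations for each cell type. The simulated genes varied independently of each other. In the data the estimated correlation within a list was as high as 0.674 in macrophages and 0.642 in CD8 T cells, for ribosomal proteins. The simulation therefore does not show how camera behaves on lists whose genes vary together. For the marker lists, 79 of 80 moved lists were found and 2 of 160 unmoved lists were called. Other work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.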

Results

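Gene expression was measured by RNA sequencing in 2 cell populations sorted from PyMT mouse breast tumours, a model in which the polyoma middle T oncogene drives mammary cancer. The tumours had been given saline or 5 ng of GM-CSF, the cytokine that drives growth and activation of macrophages and granulocytes and is encoded by Csf2. The title of the series names tumour oxygenation and anti-tumour immunity, with macrophages as the route. The comparisons therefore ask what GM-CSF changed in tumour macrophages, what it changed in CD8 T cells, the cells that kill tumour cells, and whether both responded alike. There were 3 macrophage libraries for each treatment, 3 CD8 T cell libraries with GM-CSF and 2 with saline. The estimated depth ran from 7.41e+06 to 2.23e+07 reads, and each library had between 8845 and 9588 genes at 1 RPKM or more. Pearson correlations across genes between libraries of the same group lay between 0.946 and 0.984. Levels are given as mean RPKM ± SD over the libraries of a group, and changes are fitted log2 differences of RPKM + 1 between GM-CSF and saline.

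The sorted populations carried the genes of their cell type. Apoe and Lyz2, a lipid carrier and the lysozyme of myeloid cells, stood at 15067 ± 5681 and 6510 ± 1593 RPKM in the 6 macrophage libraries and at 7.19 ± 5.69 and 1.85 ± 1.30 in the 5 CD8 T cell libraries. Cd3g and Cd8b1, a chain of the T cell receptor complex and a chain of CD8, stood at 3600 ± 258 and 2005 ± 276 RPKM in CD8 T cells and at 22.6 ± 39.0 and 4.41 ± 8.19 in macrophages. Of 12 marker lists, 4 were higher in macrophages and 6 in CD8 T cells by an exact two-sided permutation test. Macrophage markers were higher in macrophages by a mean of 8.18 log2 units and neutrophil markers by 3.35, tumour epithelial markers by 0.48 and fibroblast markers by 0.11, each with adjusted p = 0.00649 by the exact permutation test, and all 6 macrophage libraries lay above all 5 CD8 T cell libraries for each of these lists. The members of the epithelial list went both ways, with Trf, which encodes transferrin, at 676 ± 138 RPKM in macrophages and 1.64 ± 0.871 in CD8 T cells, and Spint2 at 2.87 ± 1.83 and 53.6 ± 11.9. In the other direction, macrophages minus CD8 T cells gave -8.54 for CD8 markers, -6.65 for T cell markers, -2.28 for NK cell markers and -1.58 for CD4 and regulatory T cell markers, with the same adjusted p of 0.00649 by the exact permutation test. B and plasma cell markers (-0.89, adjusted p = 0.0115) and endothelial markers (-0.08, adjusted p = 0.0260) also passed the exact permutation test, while dendritic cell markers (-0.07) and erythroid markers (-0.05) did not, both with adjusted p = 0.606. The sign of the endothelial difference turned with a pseudocount of 0.1 and with median-of-ratios scaling, which gave 0.23 and 0.01. Dendritic cell markers turned and passed with a pseudocount of 0.1, at 0.62.

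**Figure D1:**
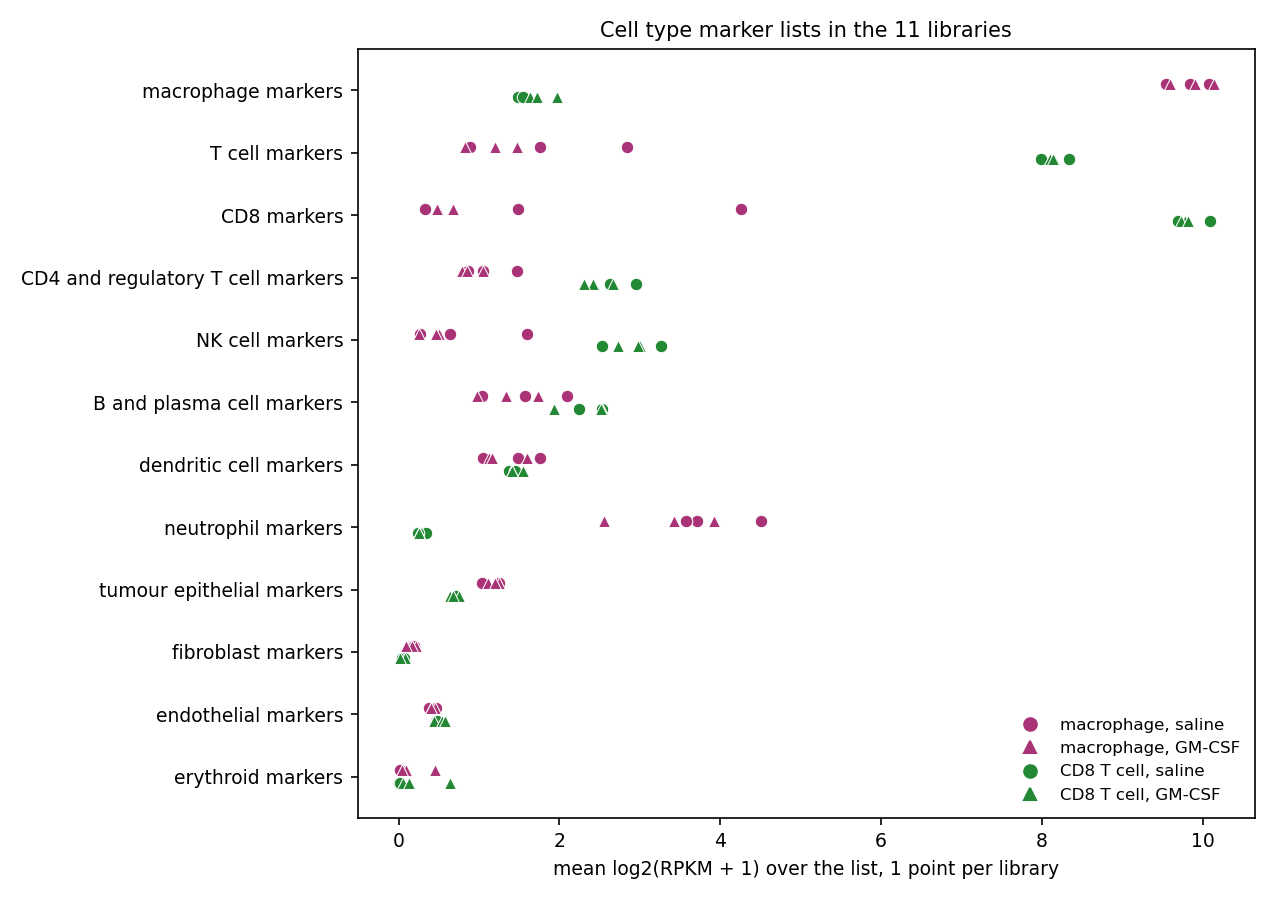
Mean log2(RPKM + 1) over the genes of each of 12 cell type marker lists, with a point for each of the 6 macrophage and 5 CD8 T cell libraries. Macrophage markers averaged 9.85 in macrophages and 1.67 in CD8 T cells, and T cell markers averaged 8.14 in CD8 T cells.

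The macrophage sort also held genes of other cells, to different extents in different libraries. Retnlg, a neutrophil gene, stood at 4705 RPKM in saline replicate 2 and at 364 to 2260 in the other 5 macrophage libraries. S100a8, another neutrophil gene, was also highest in saline replicate 2, at 425 RPKM. In GM-CSF replicate 3, with Retnlg at 2260, S100a8 was at 63.9 and the neutrophil gene Csf3r at 3.84. Retnlg therefore did not follow them in each library, and which cells gave its reads was not tested. Cd3g reached 101 RPKM in saline replicate 2, against 16.5 in saline replicate 3 and 1.21 to 8.46 with GM-CSF. Cd8b1 in that library was 21.1 RPKM. From the T cell markers, the share of T cell RNA was estimated at 1.90% in saline replicate 2, 0.139% and 0.469% in saline replicates 1 and 3, and 0.201%, 0.354% and 0.0541% in GM-CSF replicates 1 to 3.

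In macrophages, 1 single gene passed between GM-CSF and saline, and 8 lists passed camera with its preset correlation, none of them with an estimated correlation. Proliferation genes, which copy DNA and run mitosis, rose by camera, with 35 of 36 measured members higher and a median log2 change of 0.54 (adjusted p = 0.559 with an estimated correlation). Interferon response genes, the antiviral and immune genes switched on by interferons, fell by camera, with 42 of 43 lower and a median of -0.40 (adjusted p = 0.559 with an estimated correlation). For both lists the libraries of the groups overlapped, and neutrophil and T cell markers fell beside them. Genes of MHC class I presentation, which display peptides to CD8 T cells, fell by camera, with 17 of 19 lower and a median of -0.29 (adjusted p = 0.559 with an estimated correlation). Genes of oxidative phosphorylation, the respiratory chain and ATP synthase of mitochondria, rose by camera by a median of 0.19, with 51 of 53 higher (adjusted p = 0.559 with an estimated correlation). For these 2 lists the libraries of the groups lay apart. For oxidative phosphorylation they did so narrowly, with list means of 7.628 in the lowest GM-CSF library and 7.621 in the highest saline library. The groups also lay apart for apoptosis and p53 response, and for the GM-CSF and STAT5 response list, which did not pass. By chance groups of 3 lie apart in 10% of cases.

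Over 9172 genes, limma called 1 gene higher with GM-CSF and 0 lower, and 162 genes had an unadjusted p under 0.05 (72 higher, 90 lower) where 459 would be expected by chance. That number was 794 with arrayWeights and 299 with the replicate number as a block, so its place against chance depends on the fit. Groups did not overlap for 615 genes or 6.71%, where chance gives 10%. The called gene was Ighd4-1 (Entrez 777661, chr12:113430528-113430538 in GRCm38), an 11 bp diversity segment of the immunoglobulin heavy chain locus with an adjusted p of 0.0287 in limma. It stood at 15.9, 13.7 and 5.93 RPKM in the libraries with GM-CSF and was listed at 0 in all 3 saline libraries. These values correspond to about 3, 3 and 1 reads, 7 in all, so the fitted log2 change of 3.58 depends on the pseudocount and gives no fold. The macrophage Ighd4-1 call was lost without saline replicate 1 (adjusted p = 0.182), 2 (0.0888) or 3 (0.254) and without GM-CSF replicate 1 (0.210) or 2 (0.378), and with quantile normalization (0.0646), a pseudocount of 5 (0.390) or no filter on low values (0.907), each by limma.

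Among the 8 of 26 lists that passed camera, 3 rose and 5 fell, and 0 of the 8 passed with an estimated correlation or with fry, whose smallest adjusted p was 0.668. In 7 of the lists named here the adjusted p was 0.559 with an estimated correlation, and in the ribosomal list it was 0.753. For apoptosis and p53 response the estimated correlation was 0.0145, near the preset 0.01, and that call was lost as well. Proliferation (adjusted p = 1.37e-17 by camera with the preset correlation) moved by 0.85 without saline replicate 1, the 2-tumour pool, and by 0.34 without saline replicate 2. Its members with the smallest p were Cdc20, an activator of the anaphase-promoting complex in mitosis, and Kif20a and Kif11, mitotic motor proteins. Cdc20 stood at 23.6 ± 0.830 RPKM with GM-CSF and 13.2 ± 5.03 with saline, Kif20a at 7.04 ± 0.515 and 3.82 ± 1.70, and Kif11 at 6.88 ± 3.06 and 3.02 ± 1.98. None of the 36 members passed over all genes, and none passed when adjusted over the list alone. The same held for the members of the other 7 lists, 0 of which passed over all genes or adjusted over the list alone. Genes outside the list that were named by small p, among those without overlap between groups, are given as values. Cks1b, a cyclin kinase subunit, was at 121 ± 14.5 RPKM against 72.7 ± 26.1, Asf1b, a histone chaperone, at 85.5 ± 12.9 against 51.9 ± 15.3, and Rfc4, a clamp loader subunit, at 58.0 ± 4.50 against 39.7 ± 7.14. Shcbp1 (14.1 ± 1.70 against 7.61 ± 2.12) and Zw10 (7.62 ± 1.32 against 4.10 ± 1.22) were named in the same way.

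The interferon list (adjusted p = 2.06e-10 by camera and 0.559 with an estimated correlation) had Irf7, Mx2 and Stat2 as its members with the smallest p. Irf7, the transcription factor that amplifies type I interferon, was at 23.8 ± 11.4 RPKM with GM-CSF and 48.0 ± 13.5 with saline, Mx2 at 0.962 ± 0.968 and 3.52 ± 1.41, and Stat2, which carries the interferon signal to the nucleus, at 2.04 ± 0.210 and 3.61 ± 0.230. The median of the list was -0.10 without saline replicate 2, -0.13 without GM-CSF replicate 1, where the call was lost (adjusted p = 0.0557 by camera), -0.71 without saline replicate 1 and -0.64 without GM-CSF replicate 3, and it was -0.24 with arrayWeights. For MHC class I (adjusted p = 1.61e-05 by camera and 0.559 with an estimated correlation), Tap1, a subunit of the peptide transporter, was at 27.6 ± 5.63 RPKM against 42.2 ± 4.44, H2-K1, a classical class I heavy chain, at 889 ± 56.4 against 1154 ± 76.1, and H2-Q7 at 27.3 ± 1.26 against 37.2 ± 4.17. This list passed without any single library, and its median was -0.19 without saline replicate 2. Genes outside the lists named by the same rule include Ifi27l2a, Il18bp and Ly6a. Ifi27l2a stood at 342 ± 12.6 RPKM against 504 ± 83.7, Il18bp, which neutralises interleukin 18, at 53.5 ± 4.04 against 93.7 ± 16.1, and Ly6a at 154 ± 19.7 against 295 ± 99.5.

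Oxidative phosphorylation (adjusted p = 2.13e-07 by camera and 0.559 with an estimated correlation) had as its leading members Atp5g1, a subunit of ATP synthase (102 ± 17.0 RPKM against 81.3 ± 5.37), Cox6a1, a subunit of cytochrome c oxidase (724 ± 144 against 581 ± 51.4), and Ndufa4 (427 ± 44.5 against 357 ± 30.0). Ribosomal protein genes rose by a median of 0.20, with 36 of 38 higher (adjusted p = 1.68e-05 by camera and 0.753 with an estimated correlation). Among them Rps15 stood at 620 ± 188 RPKM against 460 ± 19.2, Rps19 at 406 ± 91.9 against 327 ± 30.4 and Rplp1 at 415 ± 118 against 331 ± 13.5. GM-CSF replicate 1 was the highest macrophage library for all 3. Without it the oxidative phosphorylation list gave 0.10 (adjusted p = 0.0557 by camera) and the ribosomal list 0.03 (adjusted p = 0.692 by camera), so both calls were lost, and without saline replicate 2 the ribosomal list gave 0.12. The ribosomal call was also lost with arrayWeights (0.10, adjusted p = 0.114 by camera). Apoptosis and p53 response genes fell by a median of -0.21, with 19 of 22 lower (adjusted p = 0.00516 by camera and 0.559 with an estimated correlation). They include Gadd45a, a stress-induced growth arrest gene, at 23.5 ± 5.83 against 56.9 ± 43.4 RPKM, Ei24 at 6.66 ± 2.08 against 12.1 ± 3.59, and Bcl2l11, the pro-apoptotic protein Bim, at 5.39 ± 0.465 against 7.33 ± 0.238. That call was lost without saline replicate 2 (-0.09, adjusted p = 0.162 by camera), without GM-CSF replicate 1 (-0.12, adjusted p = 0.0626) and with arrayWeights (-0.08, adjusted p = 0.112).

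Markers of other cells fell beside these groups. Neutrophil markers fell by a median of -0.52, with 13 of 13 lower (adjusted p = 1.61e-05 by camera and 0.559 with an estimated correlation). S100a8, a calcium-binding protein of neutrophils, was at 98.6 ± 81.2 RPKM with GM-CSF and 258 ± 149 with saline, its partner S100a9 at 46.8 ± 31.5 and 99.2 ± 68.9, and Csf3r, the G-CSF receptor, at 4.60 ± 0.940 and 7.08 ± 1.60. The call was lost without GM-CSF replicate 1 (-0.27, adjusted p = 0.105 by camera) and with arrayWeights (-0.02, adjusted p = 0.746), and the median was -0.80 without saline replicate 3 and -0.33 with a pseudocount of 5. T cell markers fell by a median of -1.11, with 8 of 8 lower (adjusted p = 0.000219 by camera and 0.559 with an estimated correlation). Cd3g was at 5.14 ± 3.66 RPKM with GM-CSF and 40.1 ± 53.5 with saline, Lck, a T cell kinase, at 2.60 ± 1.13 and 10.7 ± 11.8, and Cd3e at 1.29 ± 0.421 and 6.77 ± 8.25. Without saline replicate 2 the T cell list gave -0.22 and did not pass (adjusted p = 0.256 by camera). It gave -1.98 without saline replicate 1, -0.57 without GM-CSF replicate 3, -0.73 with a pseudocount of 5 and -0.68 with no filter on low values.

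Genes for blood vessel growth were not called as a group. Angiogenic factors and inhibitors had a median of -0.16 (adjusted p = 0.0933 by camera) with 13 of 19 lower. Pgf, placental growth factor, a ligand of the VEGF receptor Flt1 (Entrez 18654, chr12:85166637-85177785), was at 8.67 ± 1.16 RPKM with GM-CSF and 20.1 ± 3.73 with saline, a ratio of 0.430. It had adjusted p = 0.999 over all genes by limma and was the 1 member past the threshold when adjusted over the list alone (adjusted p = 0.0170). Flt1, which also gives rise to a soluble VEGF trap, was at 1.34 against 2.86 RPKM, a log2 change of -0.68, and Vegfa, the main vessel growth factor, at 1.73 ± 0.272 against 3.39 ± 1.99. Both receptor chains for GM-CSF were at like levels, with Csf2ra at 296 ± 96.6 against 305 ± 75.0 RPKM and Csf2rb at 22.2 ± 11.4 against 19.7 ± 1.49, and Csf2 itself was listed at 0 in all 6 libraries. The GM-CSF and STAT5 response list had a median of -0.06 (adjusted p = 0.261 by camera), with Pim1 at 13.6 ± 4.04 against 21.0 ± 7.12 RPKM. The hypoxia response list had a median of -0.03 (adjusted p = 0.328), with Ndrg1 at 19.4 ± 2.04 against 25.6 ± 3.26 RPKM.

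The polarisation lists did not pass with all libraries and the chosen settings, and calls that other settings made are given after them. Alternative activation had a median of -0.00 (adjusted p = 0.923 by camera), with Folr2, the folate receptor of tissue macrophages, at 35.7 ± 12.1 against 16.7 ± 12.1 RPKM, and pro-inflammatory activation had a median of -0.18 (adjusted p = 0.153), with the chemokine Ccl5 at 315 ± 165 against 501 ± 318. Chemokines had a median of -0.10 (adjusted p = 0.602), with the B cell attractant Cxcl13 at 4.15 ± 1.18 against 28.2 ± 32.7 RPKM, of which 65.6 was in saline replicate 2. Complement and phagocytosis had a median of -0.07 (adjusted p = 0.111). In that list Cfb, complement factor B (Entrez 14962, chr17:34856374-34862514), was at 113 ± 21.9 against 199 ± 4.70 RPKM and was the 1 member past the threshold when adjusted over the list alone (adjusted p = 0.0325), with adjusted p = 0.999 over all genes by limma. MHC class II presentation had a median of -0.12 (adjusted p = 0.120), with H2-Ob at 9.52 ± 0.610 against 13.6 ± 4.42 RPKM. Lysosome and lipid handling had a median of -0.02 (adjusted p = 0.430), with Gpnmb at 3.36 ± 1.52 against 5.60 ± 0.583, and glycolysis a median of -0.06 (adjusted p = 0.531), with Hk3 at 9.92 ± 1.58 against 13.5 ± 3.12. For monocyte genes the median was 0.02, while the mean of -0.20 and the test (adjusted p = 0.227) pointed down. Ly6c2, the classical marker of inflammatory monocytes, was at 53.9 ± 23.1 against 124 ± 30.9 RPKM. Further genes chosen by p did not overlap between groups: Gchfr, a regulator of tetrahydrobiopterin synthesis (11.5 ± 0.945 against 5.65 ± 0.526 RPKM), Asgr2 (13.3 ± 1.63 against 7.84 ± 2.13) and Zmynd15 (29.3 ± 4.96 against 47.4 ± 8.01).

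The remaining macrophage lists did not pass camera either. Macrophage markers had a median of 0.08 (adjusted p = 0.531), tumour epithelial markers 0.03 (0.602), dendritic cell markers -0.06 (0.680), B and plasma cell markers -0.15 (0.412), CD4 and regulatory T cell markers -0.13 (0.227), mitochondrially encoded genes -0.06 (0.602) and dissociation stress genes -0.13 (0.602). Of the 162 genes at an unadjusted p under 0.05, 44.4% were higher with GM-CSF, against 59.6% after quantile normalization and 59.0% among genes with a mean of at least 5 RPKM.

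Some of these macrophage lists passed camera in other settings, and none did with an estimated correlation or with fry. Pro-inflammatory activation passed downward without saline replicate 1 (-0.32), saline replicate 3 (-0.27) or GM-CSF replicate 3 (-0.45) and with quantile normalization (-0.25), while its median was 0.04 without saline replicate 2, with the test pointing up, and -0.03 without GM-CSF replicate 1. MHC class II presentation passed downward with a pseudocount of 5 (-0.11), a mean of at least 5 RPKM (-0.12), quantile normalization (-0.13) and arrayWeights (-0.22), and without saline replicate 1 (-0.23) or GM-CSF replicate 1 (-0.17), and its median was -0.04 without saline replicate 3. Complement and phagocytosis passed with a pseudocount of 5 (-0.07), quantile normalization (-0.12) and without saline replicate 2 (-0.20). Without that library lysosome and lipid handling (-0.24), glycolysis (-0.19), dissociation stress (-0.25) and angiogenic factors (-0.11) passed as well, and angiogenic factors also without saline replicate 3 (-0.23). Monocyte genes passed downward with quantile normalization (-0.05) and without saline replicate 1 (-0.30), saline replicate 3 (-0.18) or GM-CSF replicate 3 (-0.10). Without saline replicate 1, dendritic cell (-0.46), CD4 and regulatory T cell (-0.37) and B and plasma cell markers (-0.33) passed. Without GM-CSF replicate 3, hypoxia response (-0.21) and macrophage markers (0.21) did.

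**Figure D2:**
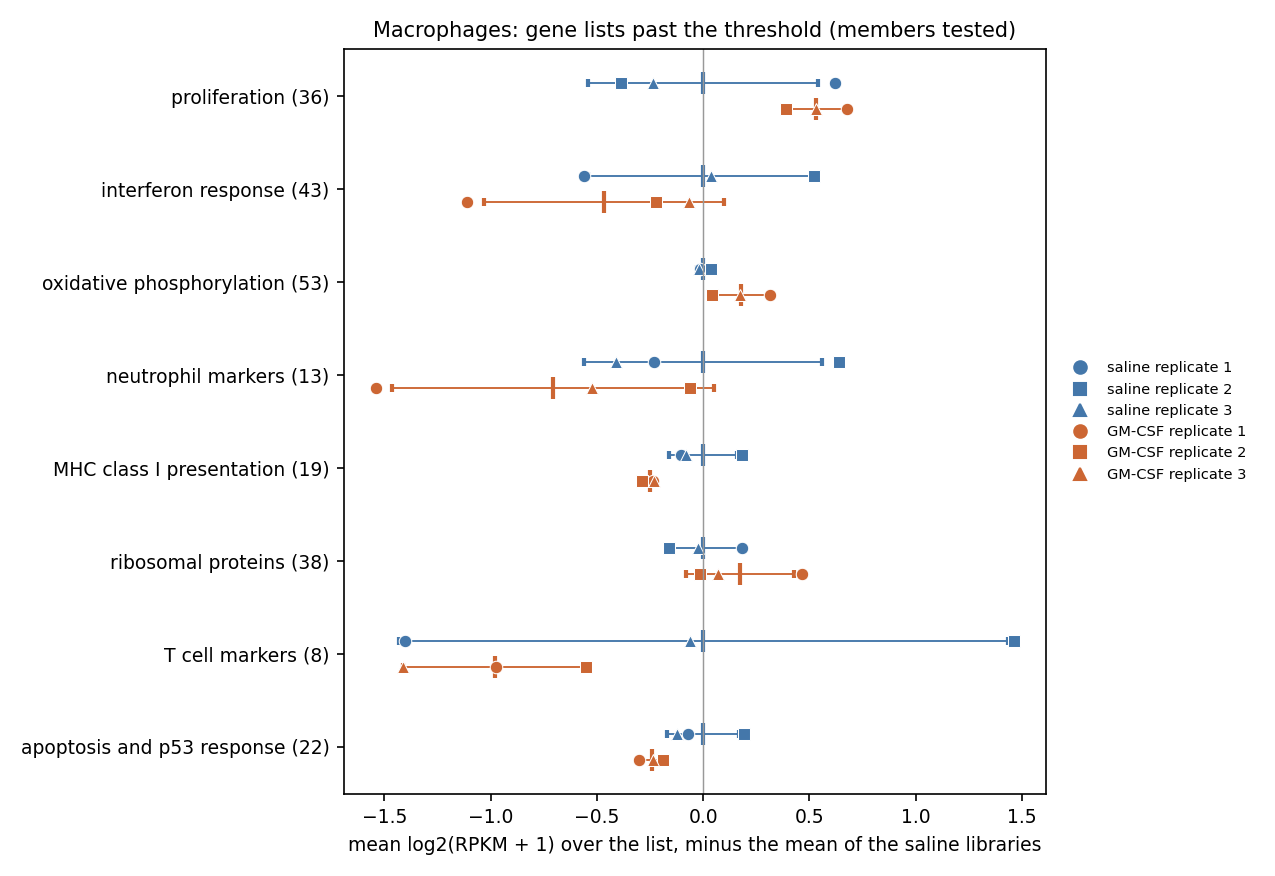
Mean log2(RPKM + 1) over the tested members of each of the 8 lists past the threshold in macrophages, minus the mean of the saline libraries, with a point for each library and bars for the mean and SD of saline (n = 3) and GM-CSF (n = 3). Saline replicate 1 lies with the GM-CSF libraries for proliferation, and saline replicate 2 lies highest for interferon response, neutrophil and T cell markers.

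In CD8 T cells, 0 single genes passed, and 10 lists passed camera with its preset correlation, none of them with an estimated correlation. The exhaustion and checkpoint list, the inhibitory receptors and regulators of repeatedly stimulated T cells, fell by camera by a median log2 change of -0.67, with 21 of 22 measured members lower (adjusted p = 0.367 with an estimated correlation). Pdcd1, which encodes the inhibitory receptor PD-1, was at 25.1 ± 3.61 RPKM with GM-CSF (n = 3) and 121 ± 42.6 with saline (n = 2), a ratio of 0.207. Cytotoxic effector genes fell by a median of -0.46, with 22 of 25 lower. Interferon response genes rose by a median of 0.36, with 32 of 41 higher. Both had adjusted p = 0.367 by camera with an estimated correlation. Beside these, mitochondrially encoded genes rose by a median of 0.36, with 13 of 13 higher, ribosomal protein genes by 0.10 and macrophage markers by 0.08. With an estimated correlation their adjusted p was 0.485, 0.847 and 0.367 by camera. Of the 10 calls, only that for interferon response held without saline replicate 1, 1 of the 2 saline libraries.

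Over 9468 genes, limma called 0 genes higher and 0 lower, with 303 at an unadjusted p under 0.05 (75 higher, 228 lower) where 473 would be expected by chance. That number was 536 with the replicate number as a block and 183 with arrayWeights, so its place against chance depends on the fit. Groups did not overlap for 1609 genes or 17.0%, where chance gives 20%. Of 23 lists, 10 passed camera, 5 up and 5 down. Of these 10, 0 passed with an estimated correlation or with fry, whose smallest adjusted p was 0.417. For activation and T cell receptor signalling (0.00145) and macrophage markers (-0.0226) the estimated correlation lay below the preset 0.01. Neither passed with it, so correlation between genes is not what ended those calls. The share of higher genes among those at an unadjusted p under 0.05 was 24.8%, against 45.5% after quantile normalization.

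The smallest adjusted p belonged to Pdcd1 (Entrez 18566, chr1:94038305-94052553), at 0.160 over all genes and 0.000372 when adjusted over the list alone by limma, with a log2 change of -2.19. With the replicate number as a block, limma gave Pdcd1 an adjusted p of 4.05e-06 over all genes and also called Lag3, Tnfrsf4, Tnfrsf9 and Tigit. Nothing in the labels says that these numbers pair the samples. Of the 22 members of the checkpoint list (adjusted p = 6.54e-10 by camera and 0.367 with an estimated correlation) 6 passed when adjusted over the list alone and 0 passed over all genes. Besides Pdcd1 these were Lag3, Tnfrsf4, Tnfrsf9, Rgs16 and Entpd1. Lag3, an inhibitory receptor that binds MHC class II (Entrez 16768, chr6:124904359-124912434), was at 5.66 ± 0.807 RPKM with GM-CSF and 24.0 ± 9.43 with saline (adjusted p = 0.00321 over the list by limma). Tnfrsf4, the costimulatory receptor OX40, was at 77.5 ± 19.7 against 180 ± 68.8 RPKM (0.0191), Tnfrsf9, the costimulatory receptor 4-1BB, at 34.5 ± 7.44 against 98.2 ± 63.9 (0.0375), Rgs16 at 19.4 against 65.3 (0.0383), and Entpd1, the ectonucleotidase CD39, at 9.14 ± 3.73 against 30.7 ± 22.1 (0.0471), each over the list by limma. The list gave -0.40 without saline replicate 1 and did not pass (adjusted p = 0.115 by camera), and gave -1.30 without saline replicate 2.

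**Figure D3:**
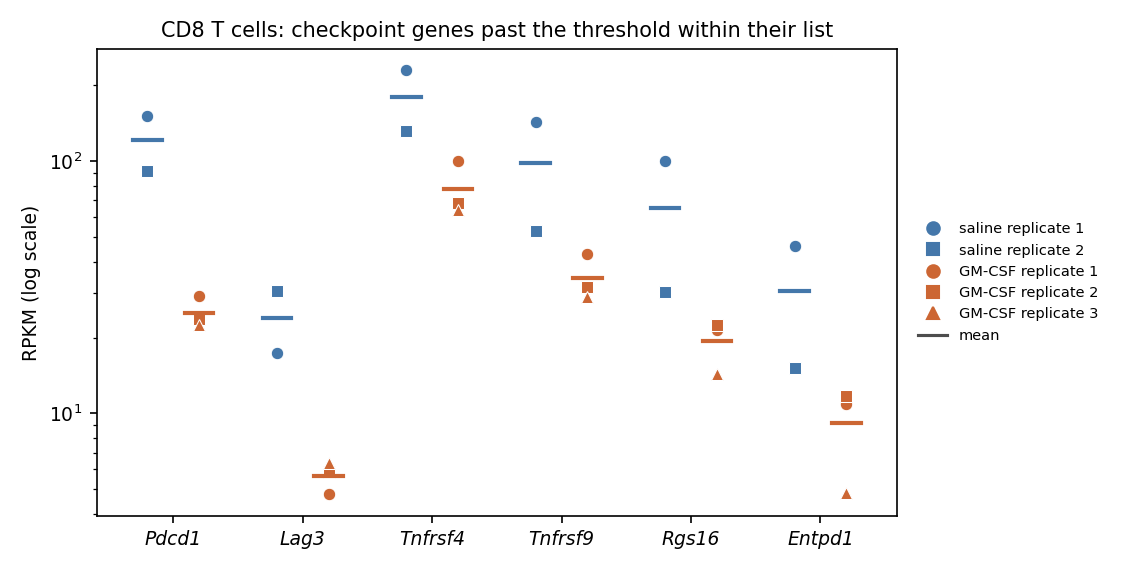
RPKM on a log axis of the 6 checkpoint genes past the threshold within their list, with a point for each CD8 T cell library and a line for the mean of saline (n = 2) and GM-CSF (n = 3). For Pdcd1 the libraries with GM-CSF lie between 22.3 and 29.2 RPKM and those with saline at 91.2 and 151.

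The cytotoxic effector list in CD8 T cells (adjusted p = 1.51e-05 by camera and 0.367 with an estimated correlation) had 0 members past the threshold over all genes and 0 when adjusted over the list alone. Prf1, which encodes perforin, was at 53.6 ± 12.5 RPKM against 104 ± 11.1, the chemokine gene Ccl4 at 199 ± 28.2 against 606 ± 440, and Ccl5 at 2414 ± 468 against 4825 ± 1982. Gzmb, which encodes granzyme B, was at 42.9 ± 19.3 against 95.9 ± 76.4 RPKM, with 150 and 41.9 in saline replicates 1 and 2, and Ifng, which encodes interferon gamma, at 50.2 ± 5.31 against 80.1 ± 57.9. The list gave -0.12 without saline replicate 1, where the call was lost (adjusted p = 0.434 by camera), and -0.73 without saline replicate 2. Activation and T cell receptor signalling genes fell by a median of -0.28, with 23 of 30 lower (adjusted p = 0.00168 by camera and 0.367 with an estimated correlation). Dusp4, a phosphatase that dampens MAP kinase signalling, was at 2.38 ± 0.729 against 8.19 ± 1.69 RPKM. Dusp4 and Tnfrsf4 passed when adjusted over the list alone, both at 0.0391 by limma, and 0 members passed over all genes. Without saline replicate 1 the list gave -0.37 and did not pass (adjusted p = 0.0892 by camera).

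Proliferation genes fell in CD8 T cells by a median of -0.27, with 31 of 36 lower (adjusted p = 0.000910 by camera and 0.559 with an estimated correlation). Aurka, a mitotic kinase, was at 7.27 ± 1.45 against 13.6 ± 2.93 RPKM, Stmn1, a microtubule regulator, at 37.4 ± 9.88 against 58.4 ± 2.46, and Cenpa, the histone of centromeres, at 56.4 ± 5.04 against 85.2 ± 23.7. The median was -0.08 without saline replicate 1, with the test pointing up (adjusted p = 0.860 by camera), -0.21 without GM-CSF replicate 2 (adjusted p = 0.202), both of which ended the call, and -0.51 without saline replicate 2. The GM-CSF and STAT5 response list fell by a median of -0.30, with 14 of 15 lower (adjusted p = 0.0113 by camera and 0.367 with an estimated correlation). Its leading members were Csf2ra, a receptor chain for GM-CSF, at 0.694 ± 0.225 against 2.88 ± 0.187 RPKM, Cish, a STAT5 target that limits cytokine signals, at 7.18 ± 0.826 against 10.5 ± 0.501, and Bcl2l1, the survival protein Bcl-xL, at 8.41 ± 1.08 against 14.3 ± 8.11. That call was lost without saline replicate 1 (-0.25, adjusted p = 0.359 by camera), without GM-CSF replicate 1 (-0.19, adjusted p = 0.0556) and with a mean of at least 5 RPKM (-0.34, adjusted p = 0.0506). Csf2 was listed at 0.408 and 0 RPKM in the saline libraries and at 0.130, 0.0946 and 0.109 with GM-CSF. In the proliferation and STAT5 lists, 0 members passed over all genes and 0 when adjusted over the list alone.

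The rise of interferon response genes (adjusted p = 1.31e-05 by camera and 0.367 with an estimated correlation) included Ifi209, a DNA-binding interferon-inducible gene, at 180 ± 23.5 against 124 ± 24.5 RPKM, and Tgtp1, an interferon-induced GTPase, at 106 ± 41.9 against 59.9 ± 2.89. It passed without any single library, with a median of 0.15 without GM-CSF replicate 3 and 0.23 without saline replicate 2. Gbp9, a guanylate-binding protein outside the list, was at 167 ± 27.3 against 105 ± 18.5 RPKM. Genes of naive and memory T cells rose by a median of 0.25, with 16 of 22 higher (adjusted p = 0.00393 by camera and 0.485 with an estimated correlation). They include Tcf7, the transcription factor TCF-1 of naive and stem-like T cells, at 318 ± 12.6 against 224 ± 16.6 RPKM, and Dapl1 at 1993 ± 424 against 1258 ± 679, while Bcl2, a survival gene, was at 31.8 ± 5.44 against 43.2 ± 4.16. The list gave -0.02 without saline replicate 1 (adjusted p = 0.665 by camera), which ended the call, and 0.13 without GM-CSF replicate 2. Mitochondrially encoded genes rose by a median of 0.36, with 13 of 13 higher (adjusted p = 1.31e-05 by camera and 0.485 with an estimated correlation). COX1, a subunit of cytochrome c oxidase, was at 2272 ± 235 against 1802 ± 232 RPKM, ND2, a subunit of complex I, at 1095 ± 197 against 801 ± 43.9, and ND5 at 560 ± 76.2 against 407 ± 0.142. That call was lost without saline replicate 1 (0.24, adjusted p = 0.295 by camera). Ribosomal protein genes rose by a median of 0.10, with 27 of 38 higher (adjusted p = 0.0271 by camera and 0.847 with an estimated correlation), with Rpl15 at 37.5 ± 3.97 against 28.5 ± 5.58 RPKM, Rps14 at 3312 ± 388 against 2750 ± 404 and Rpl5 at 45.7 ± 3.40 against 38.0 ± 1.02. The ribosomal call was lost without saline replicate 1 (-0.16), without GM-CSF replicate 3 (-0.03), with quantile normalization (0.11), with arrayWeights (0.04) and with the replicate number as a block (-0.03), and the median was 0.32 without saline replicate 2 and 0.18 without GM-CSF replicate 2. In these 4 lists 0 members passed over all genes and 0 when adjusted over the list alone.

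Macrophage markers rose in the CD8 T cell libraries by a median of 0.08, with 6 of 9 higher (adjusted p = 0.0465 by camera and 0.367 with an estimated correlation). Cd14, a receptor for bacterial lipopolysaccharide on myeloid cells, was at 2.19 ± 0.926 RPKM with GM-CSF and was listed at 0 and 0.0324 with saline, and it was the 1 member that passed when adjusted over the list alone (adjusted p = 0.0146 by limma), with 0 over all genes. C1qc was at 1.95 ± 0.418 against 0.755 ± 0.743 RPKM and Cd68 at 6.94 ± 2.69 against 12.4 ± 4.78, so these members went both ways. The call was lost without saline replicate 1 (0.03) or 2 (0.25), without GM-CSF replicate 2 (0.11) or 3 (0.01), with a pseudocount of 5 (0.07), with median-of-ratios scaling (0.11), with quantile normalization (0.15) and with a mean of at least 5 RPKM (-0.14), and the median was 0.31 without GM-CSF replicate 1 and 0.03 with arrayWeights. Lgmn, a lysosomal protease abundant in macrophages, was at 9.26 ± 0.633 against 3.92 ± 1.35 RPKM.

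The other lists did not pass in CD8 T cells with all libraries and the chosen settings. Apoptosis and p53 response (-0.15) and glycolysis (-0.16) both had adjusted p = 0.0717 by camera, with Phlda3, a p53 target, at 1.41 ± 0.270 against 4.24 ± 1.24 RPKM and Tpi1, a glycolytic enzyme, at 96.9 ± 18.0 against 151 ± 19.5. Tissue residence and homing had a median of -0.30 (0.264), with Cxcr3, a receptor for interferon-induced chemokines, at 130 ± 18.8 against 166 ± 26.1 RPKM. Hypoxia response had a median of -0.07 (0.422), with Anxa2 at 152 ± 31.7 against 298 ± 141, and oxidative phosphorylation a median of 0.04 (0.238), with Atp5d at 85.0 ± 16.8 against 137 ± 81.7. MHC class I presentation had a median of -0.06 with a test that pointed up (0.710), and Psme2, a proteasome activator, was at 508 ± 127 against 389 ± 19.5 RPKM. CD4 and regulatory T cell markers had a median of -0.30 (0.123) and tumour epithelial markers -0.13 (0.999). T cell markers (-0.01, 0.710) and B and plasma cell markers (-0.05, 0.710) had negative medians and means with tests that pointed up. So did NK cell markers (-0.01, 0.787) and dissociation stress genes (-0.11, 0.499). Dendritic cell markers had a median of -0.04, a mean of 0.09 and a test that pointed up (0.536). Camera sets a list against the other genes, and the median log2 change over all 9468 genes was -0.037. A test that points up can therefore go with a list that did not rise. Without saline replicate 2 the NK cell list turned down and passed, at -0.57 (adjusted p = 0.0313 by camera).

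Further calls in CD8 T cells came with other settings, and none with an estimated correlation or with fry. Glycolysis passed downward by camera with a pseudocount of 5 (-0.15), no filter on low values (-0.22) and a mean of at least 5 RPKM (-0.21), and its median ran from -0.38 without saline replicate 1 to -0.08 without saline replicate 2. Apoptosis and p53 response passed without saline replicate 2 (-0.26) or GM-CSF replicate 2 (-0.25). Without saline replicate 2, tissue residence and homing (-0.49), hypoxia response (-0.29), MHC class I presentation (0.19) and dissociation stress (0.46) passed too. CD4 and regulatory T cell markers passed without that library (-0.62), without GM-CSF replicate 1 (-0.44) and with no filter (-0.31), and oxidative phosphorylation without GM-CSF replicate 2 (0.11).

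Other genes of the CD8 T cells had the smallest unadjusted p without overlap between groups and are given as values. Lower with GM-CSF were Cmtm7 at 45.5 ± 2.73 against 109 ± 16.9 RPKM and Nfkbil1 at 5.46 ± 2.02 against 16.4 ± 2.97. Trgc2, a constant segment of the T cell receptor gamma chain, was lower at 33.9 ± 3.27 against 82.4 ± 36.7. Sh2d2a, an adaptor of T cell receptor signalling, was lower at 97.0 ± 24.3 against 177 ± 11.6. Hyi at 11.2 ± 1.55 against 27.9 ± 7.05 and Lilr4b at 2.66 ± 0.823 against 10.2 ± 5.68 were lower too. Higher with GM-CSF were Cd9, a tetraspanin, at 110 ± 12.3 against 66.5 ± 5.37, Selenop, a selenium carrier, at 127 ± 10.3 against 84.8 ± 9.58, Ly6k at 54.7 ± 8.80 against 30.0 ± 13.0, Rnf2 at 41.0 ± 3.70 against 23.4 ± 5.03, Nol11 at 45.2 ± 6.67 against 27.7 ± 2.26, Prps2 at 32.9 ± 1.60 against 19.9 ± 2.09 and Zfp81 at 10.5 ± 0.288 against 5.36 ± 0.00987. All had limma adjusted p of 0.922 or more.

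**Figure D4:**
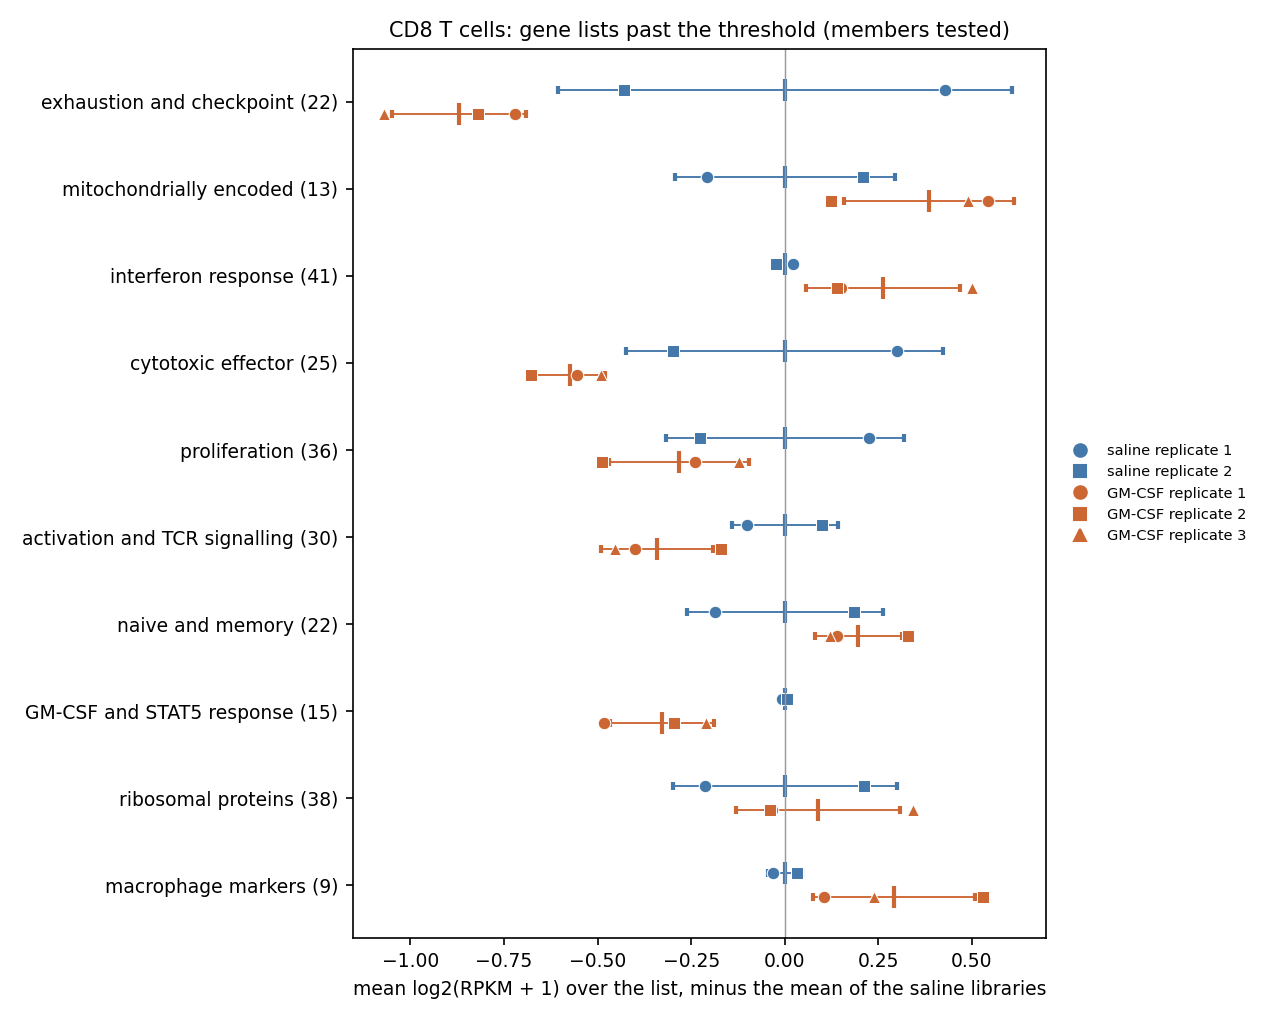
Mean log2(RPKM + 1) over the tested members of each of the 10 lists past the threshold in CD8 T cells, minus the mean of the saline libraries, with a point for each library and bars for the mean and SD of saline (n = 2) and GM-CSF (n = 3). The 2 saline libraries lie apart from each other for the exhaustion and checkpoint list, and all 3 GM-CSF libraries lie below both.

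The last comparison asked whether GM-CSF acted differently on the 2 cell types. By their medians, proliferation and interferon response genes pointed in opposite directions in the 2 cell types. Proliferation had a median of 0.54 in macrophages and -0.27 in CD8 T cells, and interferon response had medians of -0.40 and 0.36. By camera with an estimated correlation neither list passed in either cell type (adjusted p = 0.559 and 0.559 for proliferation, 0.559 and 0.367 for interferon response). The CD8 proliferation median was -0.08 without CD8 saline replicate 1. The macrophage interferon median was -0.10 without macrophage saline replicate 2. Tested on the interaction, the difference in effect, macrophages minus CD8 T cells, was 0.78 for proliferation (adjusted p = 5.05e-15 by camera and 0.632 with an estimated correlation) and -0.75 for interferon response (adjusted p = 3.24e-12 by camera and 0.632 with an estimated correlation). Both held when each of the 11 libraries was left out in turn, with ranges of 0.58 to 1.13 and -1.07 to -0.39, the last of these without macrophage GM-CSF replicate 1. With arrayWeights the interferon difference was -0.50. The other 6 lists that passed were mitochondrially encoded genes (-0.47), MHC class I presentation (-0.18), oxidative phosphorylation (0.15), and neutrophil (-0.52), T cell (-0.59) and NK cell markers (-0.43). The neutrophil value equals the macrophage median, since most of these genes stood near 0 in CD8 T cells. Their adjusted p was 0.632 to 0.735 by camera with an estimated correlation. The lists that did not pass on the interaction were the GM-CSF and STAT5 response (0.17, adjusted p = 0.385 by camera), glycolysis (0.23, 0.220), hypoxia response (0.09, 0.986), macrophage markers (-0.20, 0.112), CD4 and regulatory T cell markers (0.12, 0.890), B and plasma cell markers (-0.08, 0.294), dendritic cell markers (-0.13, 0.210), tumour epithelial markers (0.15, 0.659), dissociation stress (-0.04, 0.385) and ribosomal proteins (0.09, 0.596). Apoptosis and p53 response (adjusted p = 0.846 by camera) had a median of -0.08, a mean of 0.03 and a test that pointed down. Other settings gave calls on the interaction for macrophage markers, with a pseudocount of 0.1 (-0.35), quantile normalization (-0.25), the replicate number as a block (-0.21) and without macrophage saline replicate 2 or GM-CSF replicate 1 (-0.28 and -0.29). Without macrophage saline replicate 1, glycolysis (0.29), B and plasma cell markers (-0.27) and dendritic cell markers (-0.55) passed on the interaction, and without macrophage GM-CSF replicate 2 glycolysis (0.29) and dendritic cell markers (-0.40). Ribosomal proteins passed without CD8 saline replicate 1 (0.28) or GM-CSF replicate 3 (0.19), and dissociation stress without CD8 saline replicate 2 (-0.38). These list tests on the interaction were chosen after the data had been seen.

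Over 9944 genes, limma called 0 genes with a different effect, and 277 had an unadjusted p under 0.05, of which 66.8% had a positive difference, macrophages minus CD8 T cells, against 56.3% after quantile normalization. The genes with the smallest p and a positive difference were Ighd4-1 (3.42, adjusted p = 0.163 by limma), Tmem159 (1.16), Cmtm7 (1.42), Tctex1d2 (1.31) and Rpa2 (0.92). For Ighd4-1 the adjusted p was 0.00878 without macrophage GM-CSF replicate 3, 0.000989 with a pseudocount of 0.1 and 0.00360 with arrayWeights, by limma. Other genes were called on the interaction by limma in single settings only: Cd14 (-4.17, adjusted p = 0.00318) and Trbj1-1 (-3.80) with a pseudocount of 0.1, Cap2 (0.30), Galnt18 (0.40) and Glp1r (0.84) with no filter, and Ccl3 (3.13), Havcr2 (2.83) and Mt1 (2.62) without CD8 saline replicate 2. Cmtm7 stood at 166 ± 65.0 and 140 ± 14.9 RPKM in macrophages with GM-CSF and saline, where CD8 T cells had 45.5 ± 2.73 and 109 ± 16.9, and Rpa2, a subunit of the single-stranded DNA binding complex, at 43.3 ± 0.917 and 31.9 ± 5.94 where CD8 T cells had 113 ± 4.40 and 157 ± 8.76. Tmem159 and Tctex1d2 had fitted changes near 0 in macrophages, 0.07 and 0.03, and -1.09 and -1.28 in CD8 T cells. With a negative difference stood Cd14 (-1.55), Lgmn (-1.10), Pgf (-1.12), BC147527 (-1.42) and Abcd3 (-1.08). Cd14 and Lgmn were abundant in macrophages with either treatment, at 4577 ± 801 and 3387 ± 408 RPKM with GM-CSF and 4348 ± 391 and 3459 ± 687 with saline, and Pgf was listed at 0 in all 5 CD8 T cell libraries. BC147527 was at 7.65 ± 2.29 against 15.5 ± 5.95 RPKM in macrophages and 87.1 ± 9.01 against 60.3 ± 7.15 in CD8 T cells, and Abcd3, a peroxisomal transporter, at 5.46 ± 0.849 against 6.83 ± 0.670 and 8.49 ± 1.42 against 4.43 ± 0.649.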

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

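The difference of the GM-CSF effect between cell types was tested on 19 gene lists, and 8 passed camera with the preset correlation. These list tests, and all tests of explanations given here, were chosen after the results had been seen. Each of the 8 is named because the interaction, a test of the difference itself, passed, and 0 of them passed with an estimated correlation or with fry. Proliferation genes, which run DNA copying and mitosis, differed by a median of 0.78, macrophages minus CD8 T cells, and interferon response genes by -0.75 (adjusted p = 0.632 with an estimated correlation for both). Mitochondrially encoded genes, subunits of the respiratory chain, differed by -0.47 (adjusted p = 2.65e-05 by camera and 0.632 with an estimated correlation), and by -0.28 without CD8 saline replicate 1, where the call was lost (adjusted p = 0.0640 by camera). MHC class I presentation genes differed by -0.18 (adjusted p = 0.00996 by camera and 0.659 with an estimated correlation). That call was lost without CD8 saline replicate 1 (0.13), CD8 GM-CSF replicate 3 (-0.05), macrophage saline replicate 2 (-0.11) or macrophage GM-CSF replicate 3 (-0.20), and with arrayWeights (-0.13), and the median was -0.46 without CD8 saline replicate 2 and -0.36 without CD8 GM-CSF replicate 1. Oxidative phosphorylation genes differed by 0.15 (adjusted p = 0.0439 by camera and 0.735 with an estimated correlation). That call was lost without CD8 saline replicate 1 (0.12), CD8 GM-CSF replicate 1 (0.10) or 2 (0.12), macrophage saline replicate 1 (0.14) or 3 (0.13), or macrophage GM-CSF replicate 1 (0.08) or 3 (0.17), and the median was 0.26 without CD8 GM-CSF replicate 3.

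The other 3 differences lie in marker lists of cells that a sort carries over. T cell markers differed by -0.59 (adjusted p = 0.00490 by camera and 0.659 with an estimated correlation). That interaction call was lost without CD8 saline replicate 1 (-0.48), macrophage saline replicate 2 (-0.11) or macrophage GM-CSF replicate 3 (-0.46), and the median was -0.95 without macrophage saline replicate 1. NK cell markers differed by -0.43 (adjusted p = 0.0262 by camera and 0.659 with an estimated correlation). That call was lost without CD8 saline replicate 2 (0.14), CD8 GM-CSF replicate 1 (-0.29), macrophage saline replicate 2 (-0.13) or macrophage GM-CSF replicate 3 (-0.53), and the median was -0.96 without CD8 saline replicate 1 and -0.68 without macrophage saline replicate 1. Neutrophil markers differed by -0.52 (adjusted p = 0.00120 by camera and 0.632 with an estimated correlation), by -0.35 without macrophage GM-CSF replicate 1, where the call was lost (adjusted p = 0.0530 by camera), and by -0.95 without macrophage saline replicate 3. The neutrophil list had a mean of 0.27 log2 units in CD8 T cells, and the tested members a median change of 0 there, so the median difference equals the macrophage median and says nothing of a response of CD8 T cells. Over the members tested, T cell and NK cell markers had medians of -0.68 and -0.54 in macrophages and -0.01 and 0.00 in CD8 T cells. With arrayWeights the calls for oxidative phosphorylation (0.09), T cell markers (-0.27), NK cell markers (-0.23) and neutrophil markers (0.28) were lost. Oxidative phosphorylation was also lost with median-of-ratios scaling and with quantile normalization (0.11 in both), and NK cell markers with a pseudocount of 5 (-0.21).

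The first pattern weighed is the higher Ighd4-1 in macrophages with GM-CSF. The gene segment is 11 bp long, and 7 estimated reads with GM-CSF against 0 with saline give an exact two-sided binomial p of 0.00652. No split of 7 reads gives a smaller p, so the bound for 9172 genes, 5.45e-06, was out of reach and this test, which covers counting error only, decides nothing about few reads on a short segment. T cell RNA in the macrophage libraries with GM-CSF would have to supply 4.17% of the level of Ighd4-1 in CD8 T cells, and the highest T cell marker, Cd5, reached 1.39%, which argues against that source. Immunoglobulin heavy chain transcripts of other cells were not tested as a source. Ighm, a gene of the same locus, stood at 147 ± 29.9 RPKM in macrophages with GM-CSF and 147 ± 28.6 with saline. Few reads, such transcripts and an effect of GM-CSF itself all remain open.

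The second pattern is the lower interferon response in macrophages with GM-CSF. Saline replicate 2 carried the largest share of T cell RNA, and after each library's share had been subtracted the median of the interferon list was -0.39, where it had been -0.40, while T cell markers turned from -1.11 to 0.15. T cell RNA therefore does not account for the fall. Without saline replicate 2 the median was -0.10, and without GM-CSF replicate 1 it was -0.13 and the call ended, so either library may set most of the size of the fall. Why these libraries lay apart, in the tumour or in the handling, was not tested.

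The third pattern is the lower exhaustion and checkpoint list and the lower cytotoxic effector list in CD8 T cells with GM-CSF. Without saline replicate 1 the medians were -0.40 and -0.12, with 17 of 22 and 14 of 25 members still lower. With spreads of 0.19 and 0.17 it could not be decided whether that library sets most of the size. These spreads were taken over the genes of each list as if independent and hold no variation between libraries. Against 10000 random lists of genes of like level, both medians stood at percentile 0, outside ranges of -0.17 to 0.11 and -0.13 to 0.12. The percentile adds no support of its own. Camera had already called these lists for moving further than other genes, and the random genes were drawn independently. The random lists had medians of -0.023 and -0.0057, so a fall shared by genes of that level, as read depth might give, was not seen. Dilution by macrophage RNA would have to make up 37.2% of the libraries with GM-CSF, and the highest macrophage marker, Ctss, reached 4.89% of its macrophage level. An effect of GM-CSF and a difference between tumours in saline replicate 1 both remain open.

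The 6 macrophage libraries can be split 10 ways into groups of 3, which is too few for a share under 0.05. For genes higher with GM-CSF, 1 of the 10 splits had a count as large as the real 1, with 0 as the highest count of another split. For genes lower, all 10 splits had a count as large as the real 0, and the highest other was 0. For lists past the threshold, 7 of the 10 splits had at least the real 8, and the highest other was 15. That split put saline replicate 1 with GM-CSF replicates 1 and 3, and splits with saline replicate 1 and GM-CSF replicate 1 on the same side gave 3, 10, 12 and 15 lists. The number of lists past the threshold therefore does not set the real grouping apart from the others. These counts come from camera with its preset correlation, while the estimated correlation within a list was as high as 0.674 in macrophages. They cannot tell genes of a list that vary together from a structure among the samples. The splits with saline replicate 1 and GM-CSF replicate 1 on the same side also include the fewest lists of all.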

How the results depend on the processing

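Of the alternatives, fits without immune receptor segments, and all list tests on the interaction, were chosen after the data had been seen. With 2 or 3 libraries per group, 100 simulated genes changed 2 times were found in 38.6% of cases in macrophages and 30.2% in CD8 T cells, so smaller changes of single genes would mostly be missed. A read is worth 0.0225 to 0.0675 RPKM on a gene of 2 kb and more on a shorter one. Short genes near 1 RPKM therefore rest on few reads. Leaving out a CD8 saline library leaves 1, which is assumed to vary like the other libraries. Across the settings, 357 list values in macrophages, 283 in CD8 T cells and 339 on the interaction stayed on their side of the threshold, 26, 40 and 43 no longer passed, 27, 13 and 13 came past it, and in 0, 4 and 1 the direction of the test turned where either fit made a call. The direction of lists without a call was not compared. Lists past the threshold numbered 0 in macrophages, 0 in CD8 T cells and 0 on the interaction both with an estimated correlation and with fry, against 8, 10 and 8. That drop does not by itself show that genes of a list varied together. The 1 gene higher in macrophages became 0 with a pseudocount of 5, with no filter on low values, with quantile normalization and without immune receptor segments. Genes with a different effect numbered 3 with a pseudocount of 0.1, 3 with no filter and 1 with arrayWeights, against 0, and arrayWeights left 3 lists on the interaction.

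Without each library in turn, macrophages had 0 to 1 genes higher and 4 to 14 lists, CD8 T cells 0 to 9 genes lower and 1 to 16 lists, and the interaction 0 to 3 genes and 4 to 10 lists. The 9 lower genes, without saline replicate 2, include Pdcd1, Havcr2, Tigit, Ccl3 and Ccl4. Tests that turned were those of macrophage markers in CD8 T cells with a mean of at least 5 RPKM (-0.14), neutrophil markers on the interaction with arrayWeights (0.28), dendritic cell markers with a pseudocount of 0.1 (0.62), and endothelial markers with that pseudocount (0.23) and with median-of-ratios scaling (0.014). In CD8 T cells, leaving out a library took proliferation from -0.51 to -0.085 with a test that turned, NK cell markers from -0.57 to 0.37 and ribosomal proteins from -0.16 to 0.32. Medians also changed sign, with tests that did not, for MHC class I (0.13) and NK cell markers (0.14) on the interaction, without CD8 saline replicate 1 and 2, and in CD8 T cells for naive and memory genes (-0.02) without saline replicate 1 and ribosomal proteins (-0.03) without GM-CSF replicate 3 and with the replicate block. The cause was not tested.

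With the replicate number as a block, macrophages had 1 gene higher, 0 lower and 8 lists, CD8 T cells 3 higher, 16 lower (among them Pdcd1, Lag3, Gzmb and Tigit) and 9 lists, and the interaction 0 genes and 9 lists. Deviations of libraries with the same number correlated at 0.43, 0.28 and -0.30 in macrophages and at 0.25 and 0.08 in CD8 T cells. Not every macrophage library correlated best with its own number. These few values cannot decide whether the numbers pair the samples. In CD8 T cells, centring 2 saline libraries makes their deviations mirror each other. Whether macrophage and CD8 T cell libraries of the same number share a tumour was not tested.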

Other observations

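Transcripts of the receptor for GM-CSF were far more abundant in macrophages than in CD8 T cells. Csf2ra, its binding chain, stood at 300 ± 77.5 RPKM in the 6 macrophage libraries and 1.57 ± 1.21 in the 5 CD8 T cell libraries, and Csf2rb, its signalling chain, at 21.0 ± 7.40 and 0.150. The 5 most abundant macrophage transcripts were Cd74, the invariant chain of MHC class II, at 41970 ± 6451 RPKM, H2-Ab1 and H2-Aa, class II chains, at 25349 ± 4141 and 15559 ± 1873, Apoe at 15067 ± 5681 and Fth1, a ferritin chain, at 14987 ± 2442. Arg1, which consumes arginine, was at 624 ± 276, Spp1, which encodes osteopontin, at 4541 ± 842, and Il1b at 661 ± 113. In CD8 T cells B2m, the light chain of MHC class I, led at 11710 ± 2098 RPKM, with Nkg7, a gene of cytotoxic granules, at 5734 ± 1154.

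Some effector and checkpoint genes stood at different levels in the 2 CD8 saline libraries, with no test of the difference. Replicates 1 and 2 had Ccl3 at 396 and 62.9 RPKM, Tigit at 492 and 131, Havcr2, which encodes TIM-3, at 37.5 and 4.15, and Gzmb at 150 and 41.9, while Lag3 went the other way, at 17.3 and 30.6, and Prf1 was at 112 and 96.1. Gzma, which encodes granzyme A, was at 114 RPKM in CD8 GM-CSF replicate 3.

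Gapdh stood at 9.59 ± 3.15 RPKM in macrophages, beside Actb and Aldoa, further genes of the cell skeleton and of glycolysis, at 2876 ± 690 and 1488 ± 159 in the same libraries.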
